A study of Homo sapiens with 9 samples.

How the data were processed

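RNA from MM.1S cells, a human multiple myeloma line that grows in culture, was measured by RNA sequencing in 9 libraries. Per the labels, the cells received epigallocatechin gallate (EGCG, the main catechin of green tea) at 0, 40 or 80 µM for 24 h, with 3 libraries per dose. The libraries without EGCG are called the control. Total RNA was purified on columns and made into Illumina libraries, per the labels' protocols. Whether messenger RNA was selected by its poly(A) tail or ribosomal RNA was removed is not given in the sources used here, nor is the strand setting of the counting. The labels do not say that the replicates were separate cultures, so every p-value measures only the spread between these libraries.

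The authors deposited 1 table with a count and an FPKM per gene and library, per the file headers. The deposited count values are whole numbers per gene with no normalization. The deposited FPKM values are scaled by gene length and library size. They were used to check the counts and entered no test. The submitters' processing notes name CASAVA 1.8, HISAT2, SAMtools 1.3.1, edgeR and the GRCh38 assembly, without the role or order of each. The annotation release and the counting program are not given in the sources used here. The table lists 60675 Ensembl gene IDs, of which 60419 carry a symbol and 58444 are in GENCODE 29. Positions are GRCh38 coordinates from GENCODE 29. Counts of 0 in every library were found for 25326 IDs.

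Library totals ran from 12674490 to 16427343 counts. A floor of 3 counts in 1 library corresponds to 0.183 to 0.237 CPM (counts scaled to library size, as edgeR defines the unit), and intervals given for ratios of counts are exact binomial 95% intervals that cover counting error only. Genes were filtered with filterByExpr by group, which kept 15982 genes holding 99.71 to 99.83% of each library's counts. Libraries were scaled by TMM, with factors from 0.945 to 1.031. The common biological coefficient of variation was 0.187. No pair of replicates was a copy of another, since the spread between replicates was 12.71 to 33.21 times counting noise (chi-square per degree of freedom).

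Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to all 9 libraries with dose as the single factor and 6 residual degrees of freedom. All 3 groups shared 1 dispersion estimate because 3 libraries per group give few degrees of freedom. The comparisons were 40 µM against control, 80 µM against control and 80 µM against 40 µM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a second count took called genes with a change of 2-fold or more. Every adjusted p for a gene below comes from this test unless another is named. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the test's F statistic. CPM values are means ± SD over 3 libraries.

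Before the data were examined, 32 gene lists were fixed. They cover NRF2 antioxidant targets, metallothioneins, iron handling, integrated stress response (ATF4) targets, ER chaperones and ERAD, the cytosolic heat shock response, p53 targets, pro-apoptotic factors and anti-apoptotic factors. Further lists cover G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, MYC and nucleolar targets, cholesterol biosynthesis with LDL uptake, fatty acid synthesis, and hypoxia and glycolysis. NF-kB targets, interferon-stimulated genes, autophagy and lysosome genes, 26S proteasome subunits, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and mitochondrially encoded genes were also listed. The remaining lists hold plasma cell and myeloma identity genes, aryl hydrocarbon receptor targets, immediate early genes, EGCG binding and efflux genes and nuclear retained RNAs. Markers of mature B cells, T and NK cells, monocytes and macrophages, and stromal cells complete the set. Lists with at least 5 tested members, 26 in all, were tested against the other genes with camera from limma 3.58.1. Its inter-gene correlation was preset to 0.01, its test was two-sided, and its p-values were adjusted over the lists of each comparison. The same test with each list's estimated correlation and the rotation test fry were run beside it. Of the lists called with the preset, those that also held with an estimated correlation were 6 of 10 at 40 µM, 7 of 13 at 80 µM and 7 of 15 between the doses. Counts of called members are given over all genes tested and adjusted over the list alone.

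The rule for named genes was also fixed before the data were examined. It took, per comparison with control, the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5, a symbol that is not a clone name, and no overlap between the groups' libraries. For 80 µM against 40 µM it took 5 each way. It added the 4 members of each list with the smallest p-values. Genes that the rule took in no comparison are said to be chosen after their values were seen. A gene that the rule took in any comparison may also be given for another, without that remark. Genes on the Y chromosome and XIST were left out.

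Alternatives were run 1 at a time. They replaced TMM with RLE size factors or with library size alone, and the filter with none or with a CPM of at least 1 in 3 libraries. They replaced the test with DESeq2 1.42.0 or limma-voom, took only the libraries of the pair of groups compared, added the replicate number as a block, and left out each library in turn. After the data were seen, fits without mitochondrially encoded genes and without genes whose replicate counts lay far apart were added. Libraries with the same replicate number were not closer to each other than to others, as set out with the alternatives. The labels do not say whether equal numbers mark a shared culture or day, and this comparison cannot exclude it.

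The scripts were tested on counts simulated from the control and treated means, with 200 genes changed. The share of 2-fold changes recovered was 52.2% for 40 µM against control, 44.8% for 80 µM against control and 44.8% for 80 µM against 40 µM, and for 4-fold changes it was 90.9, 81.8 and 80.3%. For 1.5-fold changes it was 7.5, 4.5 and 7.5%. Of the simulated calls, 5.7, 6.5 and 9.3% were false. The simulations called 106, 93 and 97 genes, against 368, 5574 and 3674 in the data. The Benjamini-Hochberg cutoff on the unadjusted p depends on how many genes change. The shares recovered therefore hold for 200 changed genes and do not give the sensitivity of the real comparisons, least of all at 80 µM or between the doses. Other values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

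Because the strand setting is not known, reads of overlapping or antisense genes may have been shared. Values of genes with such a partner in GENCODE 29, and of genes with near-identical copies, are uncertain. Of the genes named below, PTBP1, MT1X, PHLDA3, NDUFV2, AHRR, DNMT1, CD79B, SNHG14, NIPA1, CPM, HTD2, SRXN1, HSPE1, BBC3, CFLAR, NME1, NOP56, NPIPA8, ETV5 and HSPA1B overlap an exon of another gene on the same strand. SLC7A11, NR4A1, DNAL1, NQO1, FTH1, ALDH1L2, DNAJB9, FKBP4, TNFRSF10B, CCNA2, SREBF1, BNIP3L, ICAM1, OAS1, SQSTM1, WIPI1, ELL2, ACTA2, FAP, SNHG14, ARVCF, NIPA1, CPM, WNK2, STEAP3, CEBPB, HSPE1, BBC3, BCL2L11, CASP6, BMF, CFLAR, GINS2, PLK1, NOP16, LSS, TPI1, HK2, JCHAIN, MVP-DT, DNAJB1, MX1, DDIT4, CDKN1A, SLC6A9, GARS1, FARSA, CARS1 and JAG1 overlap 1 or more genes on the opposite strand. HSPA6, HSPA1B, NPIPA8, the histone genes and the mitochondrial ribosomal RNAs are known to have near-identical copies.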

Results

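Gene expression was measured in MM.1S cells, a human multiple myeloma line, after 24 h with 0, 40 or 80 µM EGCG, a polyphenol of green tea. Each dose had 3 libraries. Total counts averaged 13810862 ± 652493 in the control, 14871067 ± 1427334 at 40 µM and 13819891 ± 1327717 at 80 µM (SD, n = 3 each). The first principal component held 43.5% of the variance and placed the 3 control libraries at -48.37 to -37.37, those at 40 µM at -15.38 to -4.80 and those at 80 µM at 50.77 to 53.99. The second held 13.7%, and 40 µM replicate 2 lay apart on it at -51.83. The submitters give the purpose as finding how EGCG promotes apoptosis of myeloma cells.

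The comparison of 40 µM with the control asks which genes respond to the lower dose. Of 24 ATF4 targets of the integrated stress response 17 rose, of 20 NRF2 targets 9 and of 24 p53 targets 6, and of 21 immediate early genes 8 fell (camera adjusted p = 0.00595, 0.0121, 0.0121 and 0.0121 with an estimated correlation). GDF15, a stress-induced cytokine, went from 0.174 ± 0.239 to 5.30 ± 0.0807 CPM (n = 3 per group). TRIB3, a pseudokinase induced by ATF4, rose from 34.5 ± 4.60 to 117 ± 7.08 CPM, a log2 fold change of 1.76 ± 0.11. HMOX1, the haem-degrading enzyme heme oxygenase, rose from 32.0 ± 5.74 to 104 ± 17.5 CPM. NR4A1, an orphan nuclear receptor of the immediate early class, fell from 17.8 ± 1.36 to 2.75 ± 0.277 CPM, and the splicing regulator PTBP1 fell from 685 ± 41.7 to 248 ± 16.3 CPM.

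Among genes with a mean of at least 5 CPM, the largest rise at 40 µM that met the naming rule was that of GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), whose log2 fold change was 4.89 ± 0.46 (adjusted p = 0.00048 by edgeR's quasi-likelihood test). It rests on 7 control counts, which give a ratio of 30.9 with a 95% interval of 14.8 to 77.7, and 6 of these lay in control replicate 2, without which the log2 fold change was 6.89 (4.29 without control replicate 1). RCAN2, a regulator of calcineurin, rose by 3.93 ± 0.54 from 6 control counts, a ratio of 15.9 with an interval of 7.08 to 44.4. SLC35F1, a member of a solute carrier family, rose by 3.29 ± 0.23 and the inducible chaperone HSPA6 by 2.92 ± 0.24. The transcription factor MKX rose by 2.81 ± 0.29 and the peptide hormone gene ADM2 by 2.59 ± 0.24. STEAP1, a membrane protein of the metalloreductase family, rose by 2.14 ± 0.29. SLC7A11, the cystine importer, rose by 2.12 ± 0.22 (ENSG00000151012, chromosome 4, 138164097 to 138242349). MAP2, a microtubule-associated protein, and CTH, which makes cysteine from cystathionine, rose by 2.01 ± 0.27 and 1.98 ± 0.19.

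By the same rule, the largest falls at 40 µM began with NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507), with a log2 fold change of -2.69 ± 0.19 (adjusted p = 7.9e-05 by edgeR's quasi-likelihood test). The immediate early transcription factor FOS fell by 2.58 ± 0.21 and the axonemal dynein light chain DNAL1 by 2.15 ± 0.23. RGS1 and RGS2, which turn off G protein signalling, fell by 1.97 ± 0.15 and 1.38 ± 0.15. DUSP1, a phosphatase of MAP kinases, fell by 1.91 ± 0.11, and HES1, a repressor induced by Notch signalling, by 1.57 ± 0.17. PTBP1 (ENSG00000011304, chromosome 19, 797075 to 812327) fell by 1.47 ± 0.09 (adjusted p = 7.4e-05 by the same test). Among the 10 falls were also the glutathione peroxidase GPX1, at -1.26 ± 0.26 (adjusted p = 0.038), and the Notch ligand DLL4, at -1.22 ± 0.24 (adjusted p = 0.031). The call of GPX1 ended in 9 of 19 alternatives and that of DLL4 in 7, among them a term that pairs replicates by number (replicate block, adjusted p = 0.0508 and 0.0551) and, for GPX1, only the 6 libraries compared (0.077). Without control replicate 1, 2 or 3, or 40 µM replicate 2 or 3, or 80 µM replicate 1, the adjusted p of GPX1 was 0.0838, 0.0629, 0.121, 0.116, 0.138 and 0.0594, and that of DLL4 was 0.102, 0.0542, 0.0986, 0.114, 0.117 and 0.0532. GPX1 also missed the threshold without 80 µM replicate 2, at 0.0576.

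**Figure D1:**
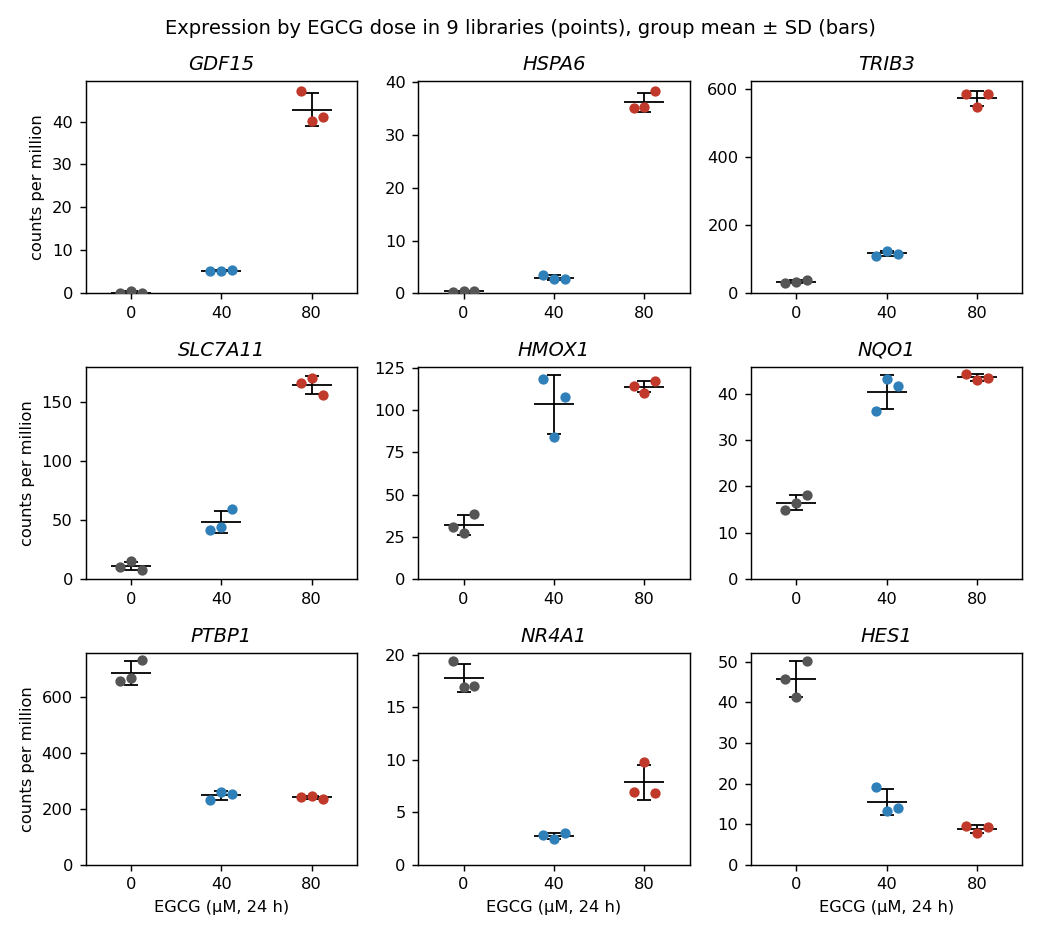
Expression in CPM (vertical axes, linear from 0) of 9 named genes against EGCG dose in µM after 24 h. Points are the 9 libraries and bars the group mean ± SD of 3. GDF15, HSPA6, TRIB3 and SLC7A11 were higher at each dose, HMOX1 and NQO1 lay at 104 and 40.4 CPM at 40 µM and at 114 and 43.5 CPM at 80 µM, and NR4A1 had its lowest mean, 2.75 CPM, at 40 µM.

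Of 24 tested ATF4 targets, which serve amino acid supply and the stress response, 17 rose, 1 fell and 6 did not pass at 40 µM. Adjusted over the list alone, 18 rose and 1 fell. ALDH1L2 and PSAT1, enzymes of folate and serine metabolism, rose by 1.95 ± 0.13 and 1.47 ± 0.10, and the transcription factor CEBPB by 1.08 ± 0.12. DDIT4, an inhibitor of mTOR signalling that was chosen after its values were seen, was the member that fell, by 1.13 ± 0.15. The list's median log2 fold change was 0.83, called by camera at an adjusted p of 3.2e-31 and at 0.00595 with an estimated correlation.

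Of 20 NRF2 targets, 9 rose and none fell, and 13 rose when adjusted over the list alone. HMOX1 rose by 1.69 ± 0.16, the quinone reductase NQO1 by 1.29 ± 0.12 and PIR, an iron-binding nuclear protein, by 1.25 ± 0.17. The median was 0.54 (camera adjusted p = 1.8e-16, and 0.0121 with an estimated correlation). Of 11 iron handling genes, 3 rose, the same number as adjusted over the list alone, and the rest did not pass. The iron storage subunit FTH1 rose by 1.10 ± 0.10 and the transferrin receptor TFRC by 1.04 ± 0.12 (list median 0.19, camera adjusted p = 1.4e-05, and 0.0385 with an estimated correlation). Of 24 p53 targets, 6 rose, 1 fell and 17 did not pass, and adjusted over the list alone 12 rose and 1 fell. PHLDA3, an inhibitor of AKT, rose by 1.70 ± 0.17, the death receptor TNFRSF10B by 0.83 ± 0.09 and the adrenodoxin reductase FDXR by 0.93 ± 0.17. BTG2, an antiproliferative gene, fell by 0.79 ± 0.11. The p53 list had a median of 0.36 (camera adjusted p = 8.4e-09, and 0.0121 with an estimated correlation).

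Of 21 immediate early genes, which are switched on within minutes by growth signals, 8 fell and none rose at 40 µM. Adjusted over the list alone, 12 fell. KLF2, a transcription factor of quiescence, fell by 0.96 ± 0.09 beside NR4A1, FOS and DUSP1. The median was -0.64 (camera adjusted p = 2.6e-24, and 0.0121 with an estimated correlation). Among 16 tested replication-dependent histone genes 1 fell, also adjusted over the list alone, namely the linker histone H1-2 by 1.00 ± 0.14. That list's median was -0.60 (camera adjusted p = 9.2e-05, and 0.0385 with an estimated correlation).

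A further 4 lists were called at 40 µM with the preset correlation but not with an estimated one. Of 22 ER chaperones and ERAD genes 3 rose, 6 when adjusted over the list alone, with the co-chaperone DNAJB9 at 0.91 ± 0.13 (camera adjusted p = 0.00356, and adjusted p = 0.0598 with an estimated correlation). Of 15 mitochondrially encoded genes the ribosomal RNAs MT-RNR1 and MT-RNR2 rose, by 0.98 ± 0.11 and 1.05 ± 0.14, and 4 members rose when adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.446 with an estimated correlation). No G2/M and mitosis gene of 30 was called, 3 rose adjusted over the list alone, and the list's median was 0.18 (camera adjusted p = 0.0125, and adjusted p = 0.425 with an estimated correlation). That call ended without control replicate 3 (adjusted p = 0.0795) or 40 µM replicate 2 (adjusted p = 0.0627). No gene of 44 in the nuclear-encoded respiratory chain was called on either basis, the median was -0.13 (camera adjusted p = 0.0320, and adjusted p = 0.678 with an estimated correlation), and the call ended without control replicate 3 (0.293) or 40 µM replicate 3 (0.304).

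The other 16 tested lists were not called at 40 µM. HSPA6 was the 1 member of 18 heat shock genes that rose, and adjusted over the list alone 1 rose and 1 fell (median 0.11, camera adjusted p = 0.27). Of 25 pro-apoptotic genes TNFRSF10B, already counted among the p53 targets, rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.108). None of 9 anti-apoptotic, 31 G1/S, 16 NF-kB, 32 proteasome, 50 ribosomal protein or 12 nuclear retained genes was called. Adjusted over the list alone, 2 anti-apoptotic genes rose and 3 fell, 1 NF-kB target fell and 1 nuclear retained RNA rose (camera adjusted p = 0.318, 0.491, 0.194, 0.332, 0.768 and 0.755 for the 6 lists in that order). Fatty acid synthesis came to an adjusted p of 0.0503 by camera, with 1 of 13 members higher and 2 lower, 5 lower adjusted over the list alone. SREBF1, the master regulator of lipid synthesis, was among them at -0.84 ± 0.11.

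One or 2 members were called in each of the remaining lists at 40 µM. They were 1 up and 1 down of 30 MYC and nucleolar targets (camera adjusted p = 0.105), 1 up and 1 down of 24 cholesterol genes (0.491), 2 up of 30 hypoxia and glycolysis genes (0.383), 1 up of 21 interferon-stimulated genes (0.27), 2 up of 29 autophagy genes (0.962), 1 up of 23 plasma cell genes (0.383) and 1 up of 8 EGCG binding and efflux genes (0.768). The interferon-induced OAS3 rose by 1.16 ± 0.17 and ABCB1, the drug efflux pump P-glycoprotein, by 1.48 ± 0.20. Adjusted over the list alone, the counts up and down were 1 and 4 for MYC targets, 3 and 4 for cholesterol, 2 and 0 for hypoxia, 4 and 0 for interferon, 3 and 0 for autophagy, 2 and 2 for plasma cell genes, and 1 and 2 for EGCG binding and efflux. Mean and median differed in sign for anti-apoptotic genes (0.04 and -0.21), hypoxia (0.09 and -0.02) and EGCG binding (0.06 and -0.12). The camera direction differed in sign from the median for ribosomal proteins, hypoxia and nuclear retained RNAs.

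At 40 µM, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 368 of 15982 genes, 238 higher and 130 lower, and 146 of them changed 2-fold or more, 109 up and 37 down. An unadjusted p under 0.05 was found for 3188 genes. This count was sensitive to the fit. It was 859 with DESeq2, 228 without a filter on low counts, 153 with only the 6 libraries compared and 183 with a replicate block. It was 136 without control replicate 1, 151 without control replicate 3, 173 and 144 without 40 µM replicate 2 and 3, 229 and 236 without 80 µM replicate 2 and 3, and the count at 2-fold was 95, 86 and 97 without control replicate 1, control replicate 3 and 40 µM replicate 3.

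The comparison of 80 µM with the control asks which genes respond to the higher dose. Of the ATF4, p53, NRF2 and ER lists, 21, 20, 13 and 12 members rose, where 17, 6, 9 and 3 were called higher at 40 µM (camera adjusted p at 80 µM = 0.00158, 0.00301, 0.0219 and 0.0246 with an estimated correlation). These counts are not on an equal footing, since 34.9% of all genes were called at 80 µM and 2.3% at 40 µM. Adjusted over the list alone, 22, 20, 14 and 12 members rose at 80 µM and 18, 12, 13 and 6 at 40 µM. The lists of MYC and nucleolar targets, G1/S and DNA replication, and fatty acid synthesis were lower, with medians of -0.77, -0.51 and -0.72 (camera adjusted p = 0.0049, 0.0246 and 0.0246 with an estimated correlation). GDF15 reached 42.8 ± 3.75 CPM, TRIB3 572 ± 22.6 CPM and SLC7A11 164 ± 7.50 CPM (n = 3). HSPA6 went from 0.392 ± 0.106 CPM in the control to 36.3 ± 1.81 CPM. RGS1 fell from 545 ± 101 to 84.7 ± 8.23 CPM and HES1 from 45.8 ± 4.43 to 8.88 ± 0.988 CPM. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 together took 4.27 ± 0.349% of counts at 80 µM against 0.70 ± 0.0443% in the control.

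By the naming rule, GDF15 had the largest rise at 80 µM, 7.90 ± 0.42 on the log2 scale (adjusted p = 1.6e-06 by edgeR's quasi-likelihood test), a ratio of counts of 256 with a 95% interval of 124 to 637. Without control replicate 2 it was 9.91 and without control replicate 1 7.30. HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910) rose by 6.51 ± 0.21, a ratio of 94.9 with an interval of 58.2 to 166. Its near-identical neighbour HSPA7, chosen after its values were seen, went from 1 to 230 counts, a ratio of 230 with an interval of 40.8 to 9120, and reads may have been split between this pair. RCAN2 rose by 6.35 ± 0.49, a ratio of 88.6 with an interval of 40.4 to 243. SLC35F1 rose by 5.07 ± 0.23, MKX by 4.80 ± 0.28 and ADM2 by 4.20 ± 0.24. ARVCF, a catenin of cell junctions, rose by 4.21 ± 0.24 and TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) by 4.05 ± 0.12. The magnesium transporter gene NIPA1 was higher by 4.21 ± 0.81, with counts of 11, 20 and 46 in the control, 46, 464 and 475 at 40 µM and 429, 507 and 528 at 80 µM. Without control replicate 3 it was 4.96 higher, and its CPM lay over 4-fold apart between replicates of a group. CPM, which encodes carboxypeptidase M, rose by 4.02 ± 0.43.

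RGS1 (ENSG00000090104, chromosome 1, 192575727 to 192580031) had the largest fall by the rule, with a log2 fold change of -2.69 ± 0.16 (adjusted p = 3.1e-06 by edgeR's quasi-likelihood test). The tight junction gene CGN fell by 2.65 ± 0.25 and PIK3AP1, an adaptor of phosphoinositide signalling in B cells, by 2.46 ± 0.16. HES1 fell by 2.37 ± 0.17, its relative HES6 by 2.21 ± 0.27 and DLL4 by 2.22 ± 0.26. The RNA-binding protein gene MEX3D fell by 2.34 ± 0.44, the semaphorin SEMA3G by 2.27 ± 0.18 and the kinase WNK2 by 2.16 ± 0.14. The lipid enzyme gene HTD2 lay at -2.10 ± 0.55 (adjusted p = 0.014), with control counts of 77, 205 and 457 and CPM over 4-fold apart. Its call ended with limma-voom (adjusted p = 0.0711), without control replicate 3 (-1.26, adjusted p = 0.0545) and without 80 µM replicate 3 (-1.90, adjusted p = 0.0529).

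At 80 µM 21 of 24 ATF4 targets rose, 1 fell and 2 did not pass, with 22 up and 1 down adjusted over the list alone. PSAT1 rose by 2.62 ± 0.10, ALDH1L2 by 3.27 ± 0.14 and CEBPB by 2.82 ± 0.12. SESN2, a stress-induced inhibitor of mTORC1, and CHAC1, which degrades glutathione, rose by 4.40 ± 0.37 and 2.44 ± 0.12, the first chosen after its values were seen. DDIT4 again fell, by 0.66 ± 0.15. The median was 1.78 (camera adjusted p = 1e-48, and 0.00158 with an estimated correlation).

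Of 22 ER chaperones and ERAD genes 12 rose and 1 fell, the same counts as adjusted over the list alone. DNAJB9 rose by 1.96 ± 0.14, the ERAD adaptor SEL1L by 1.19 ± 0.13 and the chaperone HSPA5 by 1.12 ± 0.09 (median 0.40, camera adjusted p = 0.000136, and 0.0246 with an estimated correlation). Of 20 NRF2 targets 13 rose and 1 fell, and adjusted over the list alone 14 rose and 1 fell. SLC7A11 rose by 3.89 ± 0.23, the sulfiredoxin SRXN1 by 1.25 ± 0.11, HMOX1 by 1.83 ± 0.16 and NQO1 by 1.40 ± 0.12 (median 1.05, camera adjusted p = 3.5e-11, and 0.0219 with an estimated correlation).

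Of 24 p53 targets 20 rose, 1 fell and 3 did not pass at 80 µM, the same counts as adjusted over the list alone. TNFRSF10B rose by 2.66 ± 0.10, PHLDA3 by 3.14 ± 0.18 and FDXR by 2.10 ± 0.17. CDKN1A, the cell cycle inhibitor p21, was chosen after its values were seen and rose by 3.11 ± 0.34. BTG2 fell by 0.66 ± 0.11. The list had a median of 1.07 (camera adjusted p = 6.6e-20, and 0.00301 with an estimated correlation).

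Among 25 pro-apoptotic genes 9 rose and 5 fell, also adjusted over the list alone. The member BCL2L11, chosen after its values were seen, had CPM over 4-fold apart between replicates of a group. Its counts were 577, 584 and 767 in the control, 3092, 470 and 497 at 40 µM and 1202, 3144 and 433 at 80 µM. BBC3, which encodes PUMA, rose by 2.66 ± 0.27, PMAIP1, which encodes NOXA, by 1.15 ± 0.24 and BMF by 0.64 ± 0.12, while the executioner caspase CASP6 fell by 0.84 ± 0.12. The list's median was 0.28 (camera adjusted p = 0.0189, and adjusted p = 0.311 with an estimated correlation), and its call ended without control replicate 1 (adjusted p = 0.0564). Of 9 anti-apoptotic genes 3 rose and 2 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.33). The caspase-8 inhibitor CFLAR rose by 1.40 ± 0.22 and BCL2 by 0.90 ± 0.12, and BIRC5, which encodes survivin, fell by 1.35 ± 0.20.

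Of 30 MYC and nucleolar targets 26 fell, 1 rose and 3 did not pass at 80 µM, the same counts as adjusted over the list alone. The nucleoside diphosphate kinase NME1 fell by 1.59 ± 0.14, the spermidine synthase SRM by 1.18 ± 0.10 and the ribosome assembly genes NOP16 and NOP56 by 1.25 ± 0.11 and 1.00 ± 0.09 (median -0.77, camera adjusted p = 8.5e-15, and 0.0049 with an estimated correlation). Of 31 G1/S and DNA replication genes 21 fell and none rose, 23 adjusted over the list alone. Cyclin CCNE1 fell by 1.29 ± 0.11, the replication factors GINS2 and MCM4 by 1.12 ± 0.11 and 1.15 ± 0.12, and E2F1 by 1.00 ± 0.12 (median -0.51, camera adjusted p = 3.1e-08, and 0.0246 with an estimated correlation). Of 30 G2/M and mitosis genes 17 fell and none rose, 20 adjusted over the list alone, with AURKB at -0.86 ± 0.11 and PLK1 at -0.79 ± 0.11 (median -0.46, camera adjusted p = 8.5e-05, and adjusted p = 0.157 with an estimated correlation).

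Of 13 fatty acid synthesis genes 9 fell and 2 rose, also adjusted over the list alone. The desaturase SCD fell by 1.62 ± 0.11, SREBF1 by 1.56 ± 0.11 and the synthase FASN by 1.19 ± 0.13, while ME1, which supplies NADPH, rose by 1.14 ± 0.13 (median -0.72, camera adjusted p = 0.000126, and 0.0246 with an estimated correlation). Of 24 cholesterol genes 11 fell and 1 rose, also adjusted over the list alone, with DHCR7 at -1.25 ± 0.11 and LSS at -1.01 ± 0.16 (median -0.32, camera adjusted p = 0.00687, and adjusted p = 0.0552 with an estimated correlation). Of 44 nuclear-encoded respiratory chain genes 24 fell and 1 rose, 29 and 1 adjusted over the list alone. ATP5MC1, of the ATP synthase ring, fell by 1.25 ± 0.13 and NDUFV2, of complex I, by 0.99 ± 0.10 (median -0.45, camera adjusted p = 1.2e-05, and adjusted p = 0.392 with an estimated correlation).

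Of 29 autophagy and lysosome genes 12 rose and 2 fell, also adjusted over the list alone. The cargo receptor SQSTM1 rose by 1.63 ± 0.12, WIPI1 by 2.16 ± 0.18 and the kinase ULK1 by 1.02 ± 0.12 (median 0.18, camera adjusted p = 0.00274, and adjusted p = 0.204 with an estimated correlation). Of 21 immediate early genes 10 fell and none rose, also adjusted over the list alone. DUSP1 fell by 1.84 ± 0.11, DUSP2, another MAP kinase phosphatase, by 1.81 ± 0.15 and FOS by 1.90 ± 0.21 (median -0.34, camera adjusted p = 0.000126, and adjusted p = 0.208 with an estimated correlation).

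**Figure D2:**
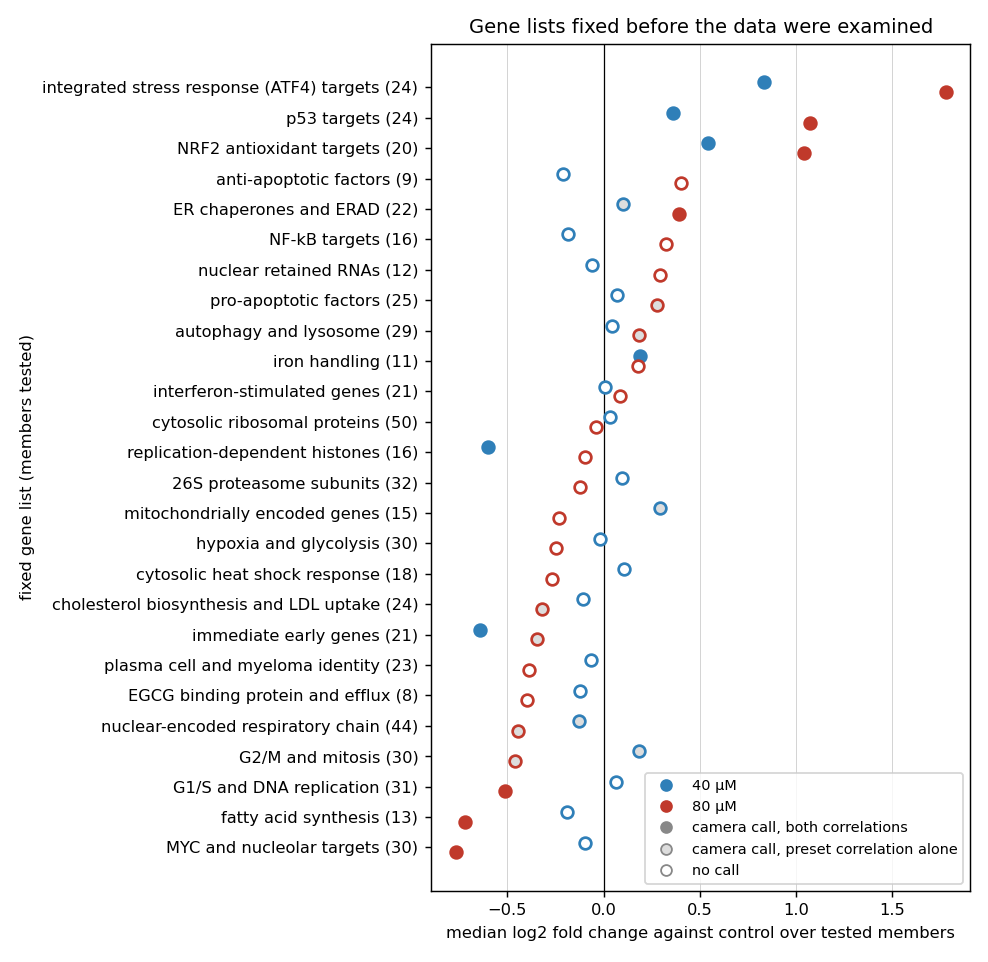
Median log2 fold change against the control over the tested members of each of 26 gene lists (horizontal axis), for 40 µM (blue) and 80 µM (red), with the number of members in parentheses. Filled points were called by camera with both correlations, grey points with the preset correlation alone, and open points were not called; ATF4 targets lie farthest right at 80 µM (1.78) and MYC and nucleolar targets farthest left (-0.77).

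The heat shock list moved in both directions at 80 µM and was not called (camera adjusted p = 0.877). Of 18 members 5 rose and 8 fell, or 5 and 9 adjusted over the list alone, with a median of -0.27 and a mean of 0.37. Beside HSPA6, the co-chaperone BAG3 rose by 0.85 ± 0.12. The stress-inducible HSPA1B, which has a near-identical copy, rose by 2.74 ± 0.47, and DNAJB1 by 0.91 ± 0.20, both chosen after their values were seen. The HSP90 co-chaperone FKBP4 fell by 1.19 ± 0.12 and the mitochondrial chaperonin subunit HSPE1 by 0.91 ± 0.13. The interferon list also split, with 7 of 21 higher and 6 lower, also adjusted over the list alone (median 0.08, camera adjusted p = 0.215). OAS1 and OAS3, sensors of double-stranded RNA, rose by 1.71 ± 0.15 and 1.72 ± 0.17 and STAT2 by 1.09 ± 0.13. The antiviral genes MX1 and IFI6, chosen after their values were seen, fell by 0.82 ± 0.15 and 1.16 ± 0.25.

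Of 15 mitochondrially encoded genes 2 rose and 4 fell at 80 µM, also adjusted over the list alone. MT-RNR1 rose by 3.10 ± 0.12 and MT-RNR2 by 2.54 ± 0.14, from 521 to 4480 and from 6507 to 37750 CPM. MT-ND3 and MT-CO2, which encode respiratory subunits, fell by 0.74 ± 0.13 and 0.61 ± 0.13. The list's median was -0.23 and its mean 0.12, and camera gave an upward direction with an adjusted p of 0.49. Counts in the 13 mitochondrial messenger RNAs made up 7.34 ± 0.431% of each control library and 6.16 ± 0.0681% at 80 µM. Counts in all protein-coding genes made up 93.1% of the control libraries, 92.2% at 40 µM and 89.4% at 80 µM.

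Of 30 hypoxia and glycolysis genes 8 rose and 12 fell, 13 of them falling when adjusted over the list alone (camera adjusted p = 0.0988). The glycolytic enzymes TPI1 and HK2 fell by 1.59 ± 0.12 and 0.87 ± 0.10, and BNIP3L, a mitophagy receptor, and the glucose transporter SLC2A3 rose by 1.41 ± 0.14 and 1.11 ± 0.12. Of 23 plasma cell and myeloma genes 4 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.0612). The transcription factor IRF4 rose by 0.72 ± 0.09 and ELL2, an elongation factor of antibody secretion, by 1.03 ± 0.13. MAF, a transcription factor active in some myelomas, fell by 0.80 ± 0.11 and the antibody joining chain JCHAIN by 0.82 ± 0.13. Of 16 NF-kB targets 6 rose and 1 fell, also adjusted over the list alone, with RELB at 1.02 ± 0.14 and ICAM1 at 0.77 ± 0.14 (camera adjusted p = 0.215). Of 8 EGCG binding and efflux genes 2 rose and 3 fell, also adjusted over the list alone. ABCB1 rose by 2.85 ± 0.20 and the methyltransferase DNMT1 fell by 0.61 ± 0.09 (median -0.40, mean 0.12, camera adjusted p = 0.877).

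Of 16 histone genes 3 rose and 4 fell at 80 µM, also adjusted over the list alone, with H2AC6 at 1.60 ± 0.31 and H1-2 at -1.15 ± 0.14 (camera adjusted p = 0.619). Iron handling had 3 genes up and 1 down of 11, also adjusted over the list alone, with FTH1 at 2.23 ± 0.11 and the ferrireductase STEAP3 at -1.52 ± 0.17 (camera adjusted p = 0.0962). Of 12 nuclear retained RNAs 3 rose and 1 fell, also adjusted over the list alone, with SNHG14 at 1.17 ± 0.16 and the kinase CLK1 at 0.92 ± 0.15 (camera adjusted p = 0.262). None of 50 ribosomal protein genes was called on either basis (camera adjusted p = 0.614). Of 32 proteasome genes 6 fell by up to 0.43, none of them when adjusted over the list alone (camera adjusted p = 0.112).

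The 6 lists with fewer than 5 tested members had no list test. At 80 µM CR2 and CD79B, markers of mature B cells, fell by 1.34 ± 0.14 and 1.19 ± 0.17, and 3 of 4 tested members of that list fell, also adjusted over the list alone. Of 3 T and NK cell markers CD3E fell, by 1.14 ± 0.27, from 4.17 CPM in the control. No monocyte or macrophage marker passed the filter. Of 3 stromal markers 2 rose at 80 µM. FAP went from 1 control count to 73, a ratio of 73 with a 95% interval of 12.7 to 2920. ACTA2 was listed at 0 in the 3 control libraries, at 12, 4 and 4 counts at 40 µM and at 10, 6 and 12 counts at 80 µM. Of the pair of metallothioneins tested MT1X fell by 1.65 ± 0.35. Of 4 aryl hydrocarbon receptor targets NQO1 alone was called, up at 40 and 80 µM, with 1 and 2 members up when adjusted over the list alone, while the receptor's repressor AHRR lay at 0.51 ± 0.98 at 80 µM (adjusted p = 0.724). None of the metallothioneins, mature B cell, T and NK cell or stromal markers was called at 40 µM, where 2 mature B cell markers fell and 2 stromal markers rose when adjusted over the list alone.

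At 80 µM, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5574 genes, 2777 higher and 2797 lower, or 34.9% of the 15982 tested. Of these 1880 changed 2-fold or more, 1135 up and 745 down. No alternative or left-out library moved either count by over 1.5 times, and leaving out 1 library gave 4170 to 5775 genes.

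**Figure D3:**
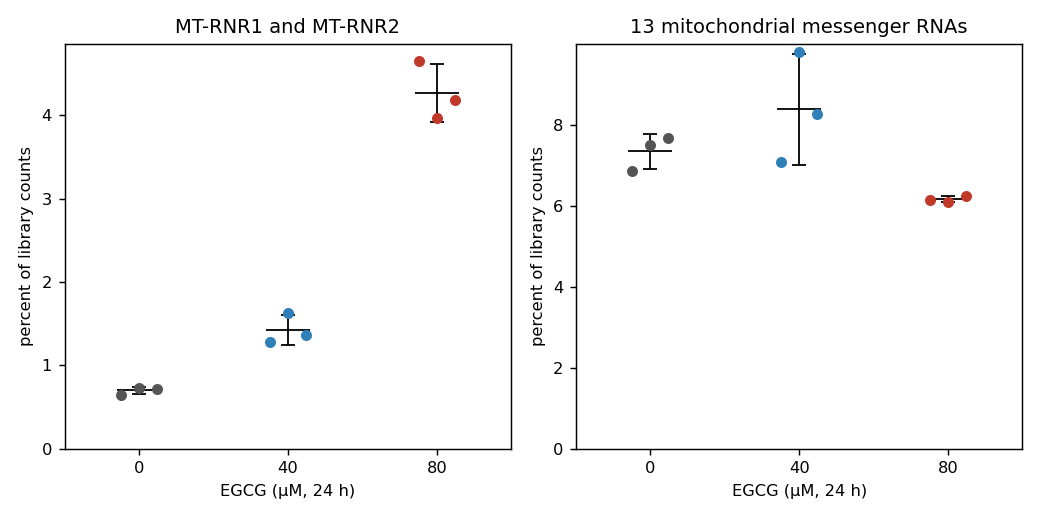
Percent of library counts (vertical axes, linear from 0) held by MT-RNR1 and MT-RNR2 (left) and by the 13 mitochondrial messenger RNAs (right) against EGCG dose in µM. Points are libraries and bars the mean ± SD of 3; the left share was 0.70% in the control, 1.43% at 40 µM and 4.27% at 80 µM, and the right share was 7.34, 8.38 and 6.16%.

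The comparison of 80 µM with 40 µM asks what the higher dose added. Between the doses 19 of 24 ATF4 targets and 18 of 24 p53 targets rose, and 28 of 31 replication, 25 of 30 mitosis and 25 of 30 MYC target genes fell (camera adjusted p = 0.00228, 0.00228, 0.00685, 0.0294 and 0.00228 with an estimated correlation). The mitosis list had a median against the control of 0.18 at 40 µM and -0.46 at 80 µM, so its fall between the doses started above the control. Neither difference from the control was called with an estimated correlation (camera adjusted p = 0.425 and 0.157). Other genes did not pass the test between the doses. HMOX1 differed by 0.14 ± 0.15 (adjusted p = 0.547 by edgeR's quasi-likelihood test), NQO1 by 0.11 ± 0.12 (0.539), PTBP1 by -0.04 ± 0.09 (0.767) and DUSP1 by 0.08 ± 0.11 (0.663). NR4A1 was higher at 80 than at 40 µM, by 1.52 ± 0.19, so its level of 7.86 ± 1.69 CPM lay between that at 40 µM and the control. DNAL1, 2.15 lower than the control at 40 µM, was 2.45 ± 0.22 higher at 80 than at 40 µM.

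By the rule, the largest rise between the doses was that of HSPA6, 3.60 ± 0.17 (adjusted p = 6.3e-06 by edgeR's quasi-likelihood test). GDF15 rose by 3.01 ± 0.27, the transcription factor CREB5 by 3.01 ± 0.53 and the p53 target ZMAT3 by 2.71 ± 0.51. ZMAT3 had counts of 168, 15 and 73 at 40 µM and 561, 605 and 389 at 80 µM, and lay at 3.52 without 40 µM replicate 1. The CPM of ZMAT3, and of NPIPA8, ZNF696 and HTD2 below, lay over 4-fold apart between replicates of a group. NPIPA8, of a multicopy gene family, was at 3.25 ± 0.98 (adjusted p = 0.037), with counts of 405, 44 and 21 at 80 µM against 21, 15 and 17 at 40 µM. Without 80 µM replicate 1 it lay at 0.88 (adjusted p = 0.23), and its call also ended without control replicate 3 (0.0524) or any library at 40 µM (0.0952, 0.107 and 0.0877), with limma-voom (0.22) and with only the 6 libraries compared (0.0617). Among the 5 largest falls by the rule were those of CGN, by 1.84 ± 0.25, the divergent transcript MVP-DT, by 1.72 ± 0.38, and PIK3AP1, by 1.69 ± 0.16. The largest was that of the zinc finger gene ZNF696, which lay at -2.23 ± 0.57 (adjusted p = 0.0191), with 40 µM counts of 52, 178 and 198, followed by HTD2 at -1.92 ± 0.55 (adjusted p = 0.0305). Without 40 µM replicate 2 or 3, or 80 µM replicate 1, 2 or 3, the adjusted p of ZNF696 was 0.0596, 0.059, 0.0616, 0.0687 and 0.0502, and that of HTD2 was 0.0789, 0.0692, 0.0671, 0.0794 and 0.103. With limma-voom both calls also ended (0.0672 and 0.0618).

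Of 24 ATF4 targets 19 rose from 40 to 80 µM and 5 did not pass, with 21 up adjusted over the list alone. TRIB3 rose by 2.29 ± 0.11, CEBPB by 1.74 ± 0.12 and PPP1R15A, which reverses translational arrest, by 1.89 ± 0.13 (list median 1.14, camera adjusted p = 4.4e-33, and 0.00228 with an estimated correlation). Of 24 p53 targets 18 rose, 19 adjusted over the list alone, with TNFRSF10B at 1.83 ± 0.09 and GADD45A at 0.88 ± 0.11 (median 0.70, camera adjusted p = 2.2e-17, and 0.00228 with an estimated correlation).

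Of 31 G1/S genes 28 fell between the doses, also adjusted over the list alone, CCNE1 by 1.18 ± 0.11 and MCM10 by 1.00 ± 0.11 (median -0.64, camera adjusted p = 2.1e-15, and 0.00685 with an estimated correlation). Of 30 G2/M genes 25 fell, 27 adjusted over the list alone, CCNA2 by 0.86 ± 0.10 and BUB1 by 0.67 ± 0.10 (median -0.60, camera adjusted p = 3.6e-13, and 0.0294 with an estimated correlation). Of 30 MYC and nucleolar targets 25 fell, 26 adjusted over the list alone, among them SRM by 0.96 ± 0.10 and the polyamine enzyme ODC1 by 0.81 ± 0.09 (median -0.68, camera adjusted p = 6.3e-19, and 0.00228 with an estimated correlation). Of 13 fatty acid genes 8 fell and 1 rose, 9 and 1 adjusted over the list alone, with SCD at -1.09 ± 0.11 (camera adjusted p = 0.000437, and 0.0294 with an estimated correlation). Of 24 cholesterol genes 7 fell, 9 adjusted over the list alone, with DHCR7 at -0.73 ± 0.11 (camera adjusted p = 0.00231, and 0.0381 with an estimated correlation).

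A further 8 lists were called between the doses with the preset correlation alone. NRF2 targets had 6 up and 1 down of 20, also adjusted over the list alone, with OSGIN1 at 2.17 ± 0.29 (camera adjusted p = 0.00176, and adjusted p = 0.136 with an estimated correlation). Of 22 ER genes 8 rose, or 8 up and 2 down adjusted over the list alone, with HSPA5 at 0.74 ± 0.09 (0.00442, and adjusted p = 0.0595 with an estimated correlation). Of 16 NF-kB targets 6 rose, or 7 up and 1 down adjusted over the list alone, with ICAM1 at 1.10 ± 0.14 (0.00577, and adjusted p = 0.0908 with an estimated correlation). Of 29 autophagy genes 10 rose, 13 adjusted over the list alone, with SQSTM1 at 1.08 ± 0.11 (8.6e-05, and adjusted p = 0.0908 with an estimated correlation). Hypoxia and glycolysis had 3 up and 8 down of 30, 4 and 14 adjusted over the list alone, with TPI1 at -1.32 ± 0.12 (0.00327, and adjusted p = 0.161 with an estimated correlation). Of 32 proteasome genes 5 fell, also adjusted over the list alone (0.00327, and adjusted p = 0.35 with an estimated correlation), and of 44 respiratory chain genes 11 fell, 12 adjusted over the list alone, with ATP5MC1 at -0.93 ± 0.13 (4.6e-05, and adjusted p = 0.365 with an estimated correlation). Anti-apoptotic genes had 4 up and 1 down of 9, also adjusted over the list alone, with BCL2 at 1.28 ± 0.12 (0.0429, and adjusted p = 0.136 with an estimated correlation). That last call ended without any 1 of the 40 µM libraries (0.0564, 0.064 and 0.0726, the first with a median of -0.06), without 80 µM replicate 1 or 3 (0.0828 and 0.0627), and without a filter (0.0865).

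The other 11 tested lists were not called between the doses. The heat shock list had 5 up and 9 down of 18 (camera adjusted p = 0.696), pro-apoptotic genes 5 up and 3 down of 25 (0.0513), histones 4 up of 16 (0.0518), interferon genes 6 up and 3 down of 21 (0.434) and plasma cell genes 3 up and 6 down of 23 (0.0579). Mitochondrially encoded genes had 2 up and 9 down of 15 (0.0729), with MT-ND3 at -0.88 ± 0.13, and iron handling 1 up and 2 down of 11 (0.584), with TFRC at -0.66 ± 0.12. Immediate early genes had 3 up and 1 down of 21 (0.075), with DUSP2 at -1.12 ± 0.15. EGCG binding and efflux genes had 2 up and 2 down of 8 (0.909), nuclear retained RNAs 3 up of 12 (0.218) and ribosomal proteins none of 50 (0.605). Adjusted over the list alone, the counts up and down were 5 and 10 for heat shock, 6 and 4 for interferon, 3 and 8 for plasma cell, 2 and 11 for mitochondrially encoded, 2 and 1 for immediate early, 2 and 3 for EGCG binding and 4 and 0 for nuclear retained genes, and unchanged for the others. Median, mean and camera direction differed in sign for heat shock (-0.33, 0.15, down), interferon genes (-0.06, -0.05, up) and EGCG binding and efflux (-0.21, 0.06, up). Of the lists without a test, mature B cell markers had 3 of 4 lower, among them CR2 at -0.94 ± 0.14, stromal markers had FAP higher, and metallothionein, aryl hydrocarbon receptor and T and NK cell members had no call, though 1 metallothionein fell when adjusted over the list alone.

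Between the doses edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3674 genes, 1746 higher and 1928 lower at 80 µM, of which 913 changed 2-fold or more, 689 up and 224 down. The count fell to 2101 without 80 µM replicate 2 and to 2288 without 80 µM replicate 3.

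The responses at both doses were compared gene by gene. Of the genes called at 40 µM, 341 were called in the same direction at 80 µM, 229 higher and 112 lower, 26 were called at 40 µM alone and 5232 at 80 µM alone. Both comparisons share the 3 control libraries. In 20 simulations all 9 libraries, the controls included, were drawn from 1 mean per gene taken over all doses. An overlap of 0 was found in each, and the deviations of the real control libraries did not enter. These simulations had a mean of 0.05 and 0 called genes at the lower and higher dose, so they had no calls to overlap and do not measure what the shared controls add to the 341. Independent lists would share 41.4 higher and 22.8 lower genes. Pearson's r of the log2 fold changes across 15982 genes, which are not independent replicates, was 0.658 against 0.502 in the simulations, and Spearman's rho was 0.575 against 0.469. The covariance was 0.275 against 0.0556 simulated, a difference of 0.219. The 3 controls cannot be divided into parts of 2 or more, so part of the excess in shared calls may come from the shared controls. With 1 control library used for 1 dose and the others for the other dose, a division chosen after seeing the data and run in all 6 ways, the covariance was 0.21 to 0.251 and Pearson's r 0.363 to 0.451. These divisions shared 50 to 358 calls in the same direction and 0 to 19 in opposite directions. The change was larger at 80 µM for 298 of the 341 genes (87.4%). Of the 229 genes higher at both doses, 149 were higher again at 80 than at 40 µM and 1 was lower, and of the 112 lower at both, 50 were lower again and 4 were higher. The overlap counted 128 to 416 genes when 1 library was left out, with 132 and 145 without control replicate 1 and 3, 160 and 128 without 40 µM replicate 2 and 3, and 227, 213 and 219 without 80 µM replicate 1, 2 and 3. It was 216 without a filter, 725 with DESeq2, 135 with only the libraries of each pair of groups and 175 with a replicate block. UVSSA, a gene of transcription-coupled repair chosen after its values were seen, was the 1 gene called in opposite directions, at -0.70 ± 0.15 at 40 µM (adjusted p = 0.0444) and 1.29 ± 0.15 at 80 µM. Its call at 40 µM ended in 13 of 19 alternatives, among them those without control replicate 1, 2 or 3 (0.0958, 0.0861 and 0.106), 40 µM replicate 1, 2 or 3 (0.055, 0.135 and 0.126) and 80 µM replicate 2 or 3 (0.0601 and 0.0749).

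**Figure D4:**
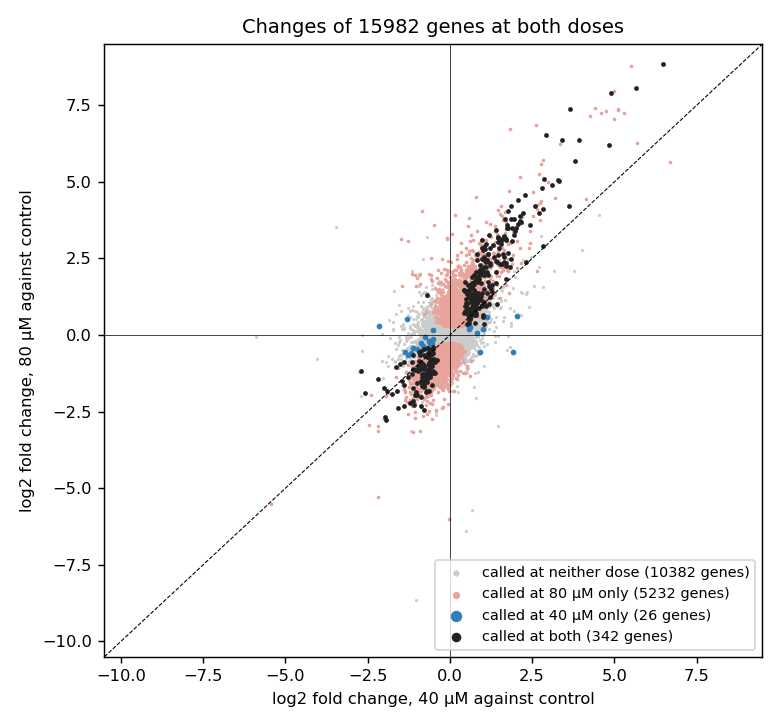
Log2 fold change against the control of 15982 genes at 40 µM (horizontal axis) and at 80 µM (vertical axis); the dashed line marks equal values. Black points are the 342 genes called at both doses and blue the 26 called at 40 µM alone. Pink marks the 5232 called at 80 µM alone and grey the genes called at neither. Both axes share the control libraries, and such sharing alone gave a mean correlation of 0.502 in simulations with all 9 libraries unchanged.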

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

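With 3 libraries per group, the p-values measure the spread between libraries that the labels number as replicates, and whether these came from separate cultures is not given in the sources used here. At 12674490 to 16427343 counts per library, genes of few counts such as GDF15 in the control carry wide intervals, and in simulated data 52.2% of 2-fold changes were found at 40 µM. The count of genes at 40 µM depended on the choice of fit and on single libraries, and the cause of these differences was not tested. Of the results for single genes, 38 of 56 called at 40 µM, 136 of 149 called at 80 µM and 87 of 109 called between the doses kept their call in every alternative. Of the called gene lists, 6 of 10, 7 of 13 and 7 of 15 did so, and no gene changed sign and no list changed its camera direction against a call. The median of anti-apoptotic factors between the doses, 0.33 as reported, was -0.06 without 40 µM replicate 1, where the list was not called. XIAP, a member of that list with CPM over 4-fold apart between replicates, had 892, 184 and 253 counts at 40 µM.

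Without a filter on low counts, 228 genes were called at 40 µM (weaker, 368 as reported) and 216 were shared between the doses (weaker, 341 as reported). With DESeq2 these were 859 and 725 (both stronger), and 359 of the 368 genes were among the 859. With only the 2 groups compared in the fit they were 153 and 135 (both weaker). With an estimated correlation, camera called 6 lists at 40 µM, 7 at 80 µM and 7 between the doses (all weaker), against 10, 13 and 15.

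With a replicate block, which pairs libraries by number, 183 genes were called at 40 µM and 175 shared between the doses (both weaker), 5069 at 80 µM and 3078 between the doses. Same-numbered libraries were not closer than others. Pearson's r of their deviations ran from -0.139 to 0.051 in 9 pairs, against -0.108 to 0.116 in other pairs, and 1 library correlated best with its own number.

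Leaving out 1 library at a time gave these ranges. At 40 µM, 136 to 469 genes were called (weaker without control replicate 1 or 3, 40 µM replicate 2 or 3, and 80 µM replicate 2 or 3) and 86 to 190 at 2-fold (weaker without control replicate 1 or 3 or 40 µM replicate 3). At 80 µM, 4170 to 5775 genes were called and 1689 to 1998 at 2-fold. Between the doses, 2101 to 4059 genes were called (weaker without 80 µM replicate 2 or 3) and 696 to 997 at 2-fold. The overlap was 128 to 416 genes (weaker for 7 of 9 libraries). Gene lists called were 9 to 11 at 40 µM, 13 to 16 at 80 µM and 14 to 18 between the doses.

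A pair of alternatives was chosen after seeing the data. With mitochondrially encoded genes removed first, 388, 5549 and 3587 genes were called at 40 µM, at 80 µM and between the doses, and with genes of switching counts removed first 433, 5673 and 3791. The share of called genes that were higher at 40 µM was 64.7% as reported, 71.9% without a filter and 54.7% with DESeq2.

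The 6 libraries of each comparison can be split in 10 ways, so no share under 0.05 can be reached. The real split called 368 genes at 40 µM and the highest other 3, 5574 and 1 at 80 µM, and 3674 and 3 between the doses. At 2-fold the values were 146 and 3, 1880 and 1, and 913 and 3. In each of these 6 results 1 split, the real one, gave a count as large. Every other split mixes libraries of both groups in each part, so the difference between the groups enters the spread and lowers the counts. The low counts of the other splits therefore do not show what unchanged libraries would give. For gene lists with the preset correlation the real and highest other counts were 10 and 8 at 40 µM, 13 and 14 at 80 µM, and 15 and 12 between the doses, with 1, 2 and 1 splits as large. With an estimated correlation they were 6, 7 and 7 against 0 in every other split.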

Other observations

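Gene lists and genes in this part were chosen after the results above were seen. The 5 added lists were tested without the members already named above or held in a fixed list, adjusted over 15 tests, and as lists picked from these libraries they are no independent evidence. Of 9 such amino acid transporters, SLC3A2, SLC7A5 and SLC7A11 being left out, 6 rose and 1 fell at 80 µM (median log2 fold change 0.79, camera adjusted p = 6e-05, and adjusted p = 0.0965 with an estimated correlation). The glycine transporter SLC6A9 rose by 1.61 ± 0.14 at 40 µM and 3.17 ± 0.14 at 80 µM, and SLC3A2, the partner chain of SLC7A11 that was left out, by 1.03 ± 0.12 and 2.44 ± 0.13. Of 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, 8 rose and 2 fell at 80 µM (median 0.32, camera adjusted p = 0.0036, and adjusted p = 0.131 with an estimated correlation). GARS1 rose by 1.61 ± 0.10 and CARS1 by 1.64 ± 0.12, while FARSA and FARSB, the chains of the phenylalanine enzyme, fell by 0.85 ± 0.14 and 0.69 ± 0.11. Of 16 selenoproteins, 4 rose and 5 fell at 80 µM (camera adjusted p = 0.889).

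Of 8 Notch pathway genes other than HES1, HES6 and DLL4, none was called at 40 µM and 3 rose at 80 µM, and the list was called at neither dose (camera adjusted p = 0.927 and 0.284). The ligand JAG1 rose by 0.75 ± 0.14 at 80 µM. Of 7 MAP kinase feedback genes other than DUSP5 and DUSP6, with ETV5 that prompted the list still in it, 4 rose and 1 fell at 80 µM (camera adjusted p = 0.0127, and adjusted p = 0.0965 with an estimated correlation). The transcription factor ETV5 rose by 1.18 ± 0.15 at 40 µM and 3.27 ± 0.15 at 80 µM, and SPRED2, an inhibitor of RAS signalling, by 1.19 ± 0.11 at 80 µM. PTBP2, the neural relative of PTBP1, lay at 1.15 ± 0.34 at 80 µM (adjusted p = 0.0236 by edgeR's quasi-likelihood test). That call ended without control replicate 1 (1.06, adjusted p = 0.0764), control replicate 3 (1.03, 0.0813) or 80 µM replicate 2 (0.66, 0.101).

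The tests of the next patterns were chosen after seeing the results. MT-RNR1 and MT-RNR2 were higher by 3.10 and 2.54 at 80 µM, while 91 other RNAs that lack poly(A) tails had a median of -0.405 (95% bootstrap interval -0.616 to -0.109). The 13 mitochondrial messenger RNAs had a median of -0.251 (-0.382 to -0.163), and with library size alone the lower of the pair was 2.56. Both intervals come from resampling the RNAs as if they were independent. The libraries were not resampled, so the spread between libraries is not covered. A general gain of tail-less RNA, of mitochondrial RNA, or the scaling between libraries would each give other values. As a hypothesis, the treated cells may hold more mitochondrial ribosomal RNA or have it tailed or degraded differently. A measurement without selection of RNA by its tail and without removal of ribosomal RNA could tell these apart. Whether ribosomal RNA was removed from these libraries is not given in the sources used here. A difference that arose in the preparation was therefore not tested and stays open.

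Of 11043 genes with at least 100 counts in some library, 201 (1.82%), NIPA1, HTD2, NPIPA8, ZMAT3 and ZNF696 among them, had CPM over 4-fold apart between replicates of a group, and the largest deviation fell on no single library, with 16 to 29 genes each. Of the 197 of them in GENCODE 29, 57.9% had an exon overlap on the same strand, against 18.2% of matched genes (permutation test, p = 0.0001, the smallest that 10000 random lists of matched genes can give), while 37.6% had one on the opposite strand, against 40.2% of matched genes (permutation test, p = 0.792). Of 106 pairs on the same strand, 72.6% deviated in opposite directions, against 46.7% of 332 other pairs. As a hypothesis, reads may have been assigned to either of a pair of genes that overlap on the same strand in different libraries, and counting the reads anew with 1 setting would test it. JUN, with counts of 143, 2351 and 123 in the control, 107, 961 and 1068 at 40 µM and 1994, 56 and 93 at 80 µM, has no such overlap and stays open.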
